A study of Rattus norvegicus with 8 samples.

How the data were processed

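Chromatin immunoprecipitation with sequencing (ChIP-seq) for H3K27ac, an acetylated form of histone H3 found at active promoters and enhancers, was carried out on rat sciatic nerve. Per the labels, male Sprague Dawley rats were operated on at postnatal day 25, the nerve of one leg was cut, and the other leg received a skin incision only as the sham. The nerve distal to the cut or sham site was taken after 72 h and fixed in 1% formaldehyde, and the chromatin was sonicated to fragments of 0.5 to 2 kb on average. Each immunoprecipitation used 300 µg of chromatin and 5 µg of antibody, and an aliquot of 10% was kept as input, per the labels' protocols. The labels give 2 H3K27ac samples and 2 inputs for the injured nerve and the same numbers for the sham nerve, and the series' design text calls the 2 samples of a condition independent. How many animals entered a sample is not given in the sources used here.

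The authors deposited 4 peak lists: 1 of H3K27ac peaks in injured nerve, 1 of H3K27ac peaks in sham nerve, and 1 list of differential peaks for each condition. The submitters' processing notes name CASAVA 1.8.2, Bowtie, HOMER and the rat build Rnor_5.0, without saying which step each was used for. The peak caller, the differential test, their thresholds and the way the 2 replicates and their inputs were combined are not given in the sources used here. Each deposited line holds a chromosome, a start, an end, a list name, a running line number and a strand sign that is always plus. The values are positions in base pairs. The lists carry no peak height, fold or p-value and no value per replicate, so the depth of each sample is unknown here and no spread between replicates could be computed. That absence limits every comparison: the 2 lists were thresholded separately, and a peak missing from a list is a peak that was not called, not a measured absence of acetylation.

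All starts lay on a grid of 100 bp, the smallest peak was 199 bp wide and the smallest gap between 2 peaks of a list was 201 bp, in all 4 lists. Starts were read as BED positions and are printed 1-based, one higher than deposited, and a width is the deposited end minus the deposited start. In 8 peaks the start or the end was written with an exponent, and each was read as the whole number it stands for. Blank lines at the ends of 3 lists were dropped. No list held a duplicate peak.

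Peaks were not assigned to genes. The gene table at hand is on another rat assembly (GRCr8), an annotation and a sequence of Rnor_5.0 were not used here, and no coordinates were converted between builds. Comparisons of promoter share, of gene lists and of sequence motifs, set out beforehand, were therefore not run, and regions are named by position, with no statement on the gene, exon or intron they lie in.

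Peaks of different lists were taken to overlap when they shared at least 1 bp. Shares of peaks are given with 95% Wilson intervals, which cover counting error over the peaks of these lists only. The Jaccard index is the base pairs in both lists over the base pairs in either. For the counts by chromosome, the 2 condition lists were merged into a union list wherever peaks overlapped, and a union peak was differential when it overlapped a differential peak. The labels were permuted 100000 times over the union peaks, and the largest standardised deviation over chromosomes was compared with the permuted ones. Each chromosome was tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over both directions and all 21 chromosomes and a threshold of 0.05. For the direction of neighbours, consecutive differential peaks at most 12500 bp apart were paired, and the number of pairs with one direction was compared, two-sided, with 10000 permutations of the directions over the differential peaks. Widths were compared on the log2 scale by 100000 permutations, two-sided. The regions named per direction are the 10 groups of differential peaks, linked at most 12500 bp apart, with the most peaks, ties broken by covered base pairs. This rule, the tests of overlap, direction, chromosome and median width, and a first set of other settings were fixed before the data were examined. Those settings were a stricter or looser overlap, peaks wider than the median only, link distances of 5 kb and 50 kb, and expected numbers by chromosome that follow covered base pairs (exact binomial test). The comparison of mean widths, the comparison of spacing with random draws and the settings named as later ones in the closing section were added after the lists had been seen.

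The procedures were tested on simulated data. On the 28114 sham peaks, an overlap of 59.5% built into a copy was recovered as 59.5%. With random directions on the 7602 differential peaks, the test of neighbours called 5% of simulations at 0.05. With random labels on the 31894 injury peaks, the chromosome test called 4% and the width test 7% of simulations. Directions and labels were drawn independently for each peak, as the tests assume. These rates therefore say nothing about labels that cluster along the genome, as the real ones did. The rates are also rough, since they rest on few simulations, each with fewer permutations than the tests of the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.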

Results

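The series profiled H3K27ac in the distal sciatic nerve of rats 72 h after the nerve was cut, beside the sham-operated nerve of the other leg, to compare enhancers between injured and uninjured peripheral nerve. The sciatic nerve holds axons wrapped by Schwann cells, the glia of peripheral nerve. It was profiled as whole tissue, without a sort, so the lists do not tell in which cells a site was acetylated. The design held 2 H3K27ac samples and 2 inputs per condition, which the series describes as independent. The deposited results were 1 peak list per condition and 1 differential list per condition, so the values below describe lists and have no replicate error. The p-values treat peaks as the units and describe these lists, not the animals behind them.

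More of the genome was called acetylated in injured than in sham nerve. The injury list held 31894 peaks covering 16.9 Mb, and the sham list held 28114 peaks covering 13.2 Mb, a ratio of 1.13 for peaks and 1.28 for base pairs. Both lists were made mostly of short intervals, with a median width of 299 bp in each. The upper quartile was 599 bp in the injury list and 499 bp in the sham list, and the widest peaks were 13499 bp and 12299 bp. Peaks over 1 kb made up 10.3% of the injury list and 7.90% of the sham list. Peaks lay on all 20 autosomes and on chromosome X. The differential lists held 4312 peaks for injury and 3290 peaks for sham, a ratio of 1.31. Because no read depth was at hand, the larger number in injured nerve could not be set against sequencing depth.

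The first comparison asked which acetylated sites injured and sham nerve had in common. Fewer than 50% of the peaks of either list overlapped the other by at least 1 bp: 12649 injury peaks (39.7%, 95% interval 39.1 to 40.2) and 13073 sham peaks (46.5%, 45.9 to 47.1). Both lists shared 6.16 Mb, a Jaccard index of 0.257, and 1269 peaks had identical borders. Overlapping peaks included, a sham peak was found within 1 kb of 52.4% of all injury peaks and within 50 kb of 84.7%, and an injury peak within 1 kb of 60.6% of all sham peaks and within 50 kb of 88.9%. Wide peaks were shared more often than narrow ones. Of the injury peaks over 1 kb, 74.0% overlapped a sham peak, against 22.5% of those at the smallest width, and in the sham list the shares were 81.8% and 27.2%. A wide peak also has more base pairs with which to meet another. The shares depended on the rule: under a reciprocal overlap of 50% they were 19.0% for injury and 21.6% for sham, and with peaks extended by 500 bp on each side 52.4% and 60.6%. With both lists cut to peaks wider than their own median they were 38.5% and 52.4%. That cut also removes the narrower peaks of the other list, so these are not the shares of wide peaks that met the full other list.

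**Figure D1:**
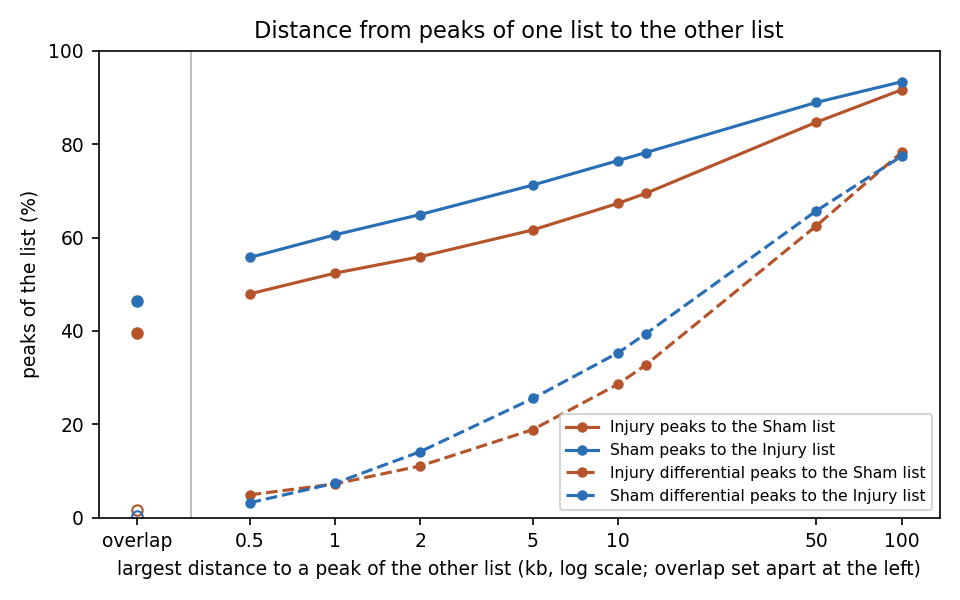
Percent of the peaks of each list (vertical axis) that had a peak of the other condition's list within a given distance in kb (horizontal axis, log scale, overlap of at least 1 bp set apart at the left). Solid lines are the full condition lists and dashed lines the differential lists. The full lists began at 39.7% and 46.5% and the differential lists at 1.67% and 0.365%. Almost all differential peaks lacked an overlap, so the full lists are not a like comparison for them.

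The differential lists named the sites at which acetylation was scored as different between injured and sham nerve. They were almost entirely sites called in one condition and not in the other. Of the 4312 injury differential peaks in the authors' deposited list, 4240 (98.3%, 97.9 to 98.7) overlapped an injury peak and no sham peak, and 70 (1.62%) overlapped both. Of the 3290 sham differential peaks in the authors' deposited list, 3278 (99.6%, 99.4 to 99.8) overlapped a sham peak and no injury peak, and 12 (0.365%) overlapped both. All 3290 sham differential peaks were, with the same borders, members of the sham list, as were 4310 of the injury differential peaks of the injury list, so these shares partly reflect how the lists were drawn. The 2 exceptions, on chromosome 2 at 210022801 to 210023099 and on chromosome 10 at 11199301 to 11199599, stood in the injury differential list but were, border for border, peaks of the sham list with no overlapping injury peak. They were singled out after their positions were seen. Injury differential peaks made up 13.5% of the injury list and 22.0% of the injury peaks without an overlapping sham peak. For the sham list the shares were 11.7% and 21.8%. The median distance was 30.2 kb from an injury differential peak to the nearest sham peak, and 23.1 kb from a sham differential peak to the nearest injury peak. Since almost none overlapped the other list, the full lists are not a like comparison. Within 1 kb, 7.26% of injury and 7.42% of sham differential peaks had a peak of the other list. Among peaks outside the differential lists that overlapped no peak of the other list, 25.4% of injury and 31.7% of sham peaks did.

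The differential peaks fell into groups, and the groups with the most peaks held many peaks of one condition and few or none of the other. The sham group with the most peaks lay on chromosome 2 at 105285601 to 105364499 (Rnor_5.0). It spanned 78.9 kb with 23 differential peaks among 28 sham peaks, and no injury peak was called in it or within 50 kb of it. The injury group with the most peaks lay on chromosome 5 at 130082501 to 130126799 and spanned 44.3 kb. It held 12 differential peaks among 16 injury peaks, and no sham peak was called in it or within 50 kb. In both conditions most differential peaks stood alone: the 4312 injury peaks formed 3206 groups, of which 757 held 2 or more peaks and 31 held 5 or more, and the 3290 sham peaks formed 2507 groups, of which 490 and 27 did.

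**Figure D2:**
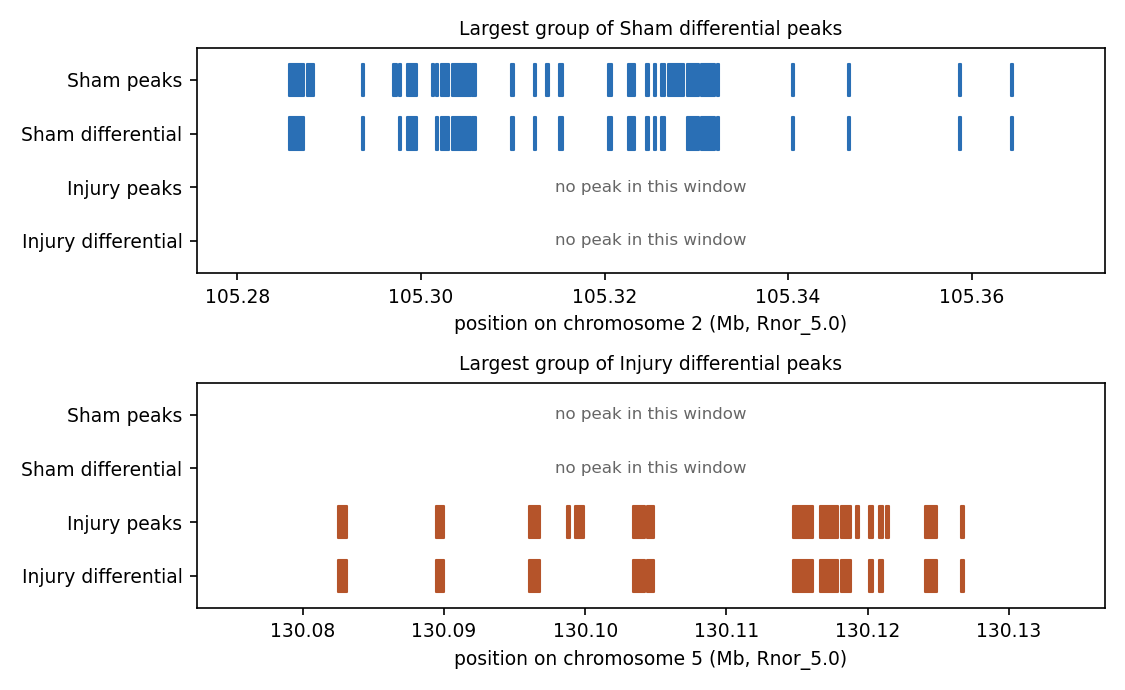
Peaks of the 4 deposited lists (rows) along the group with the most sham differential peaks on chromosome 2 (top) and the group with the most injury differential peaks on chromosome 5 (bottom), with 10 kb on each side; the horizontal axis is the position in Mb on Rnor_5.0 and each block is 1 peak drawn to scale. The sham group held 28 sham peaks and no injury peak, and the injury group held 16 injury peaks and no sham peak.

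Among the 10 injury groups with the most peaks, each held 6 to 12 differential peaks over 19.6 to 44.3 kb. Together they held 113 injury peaks and 12 sham peaks, and 5 of them held no sham peak. On chromosome 6, a group of 11 differential peaks at 155995701 to 156033699 held 23 injury and 4 sham peaks, and a group of 7 at 155846901 to 155866499 lay 129 kb from it. Groups also lay near each other on chromosome 1, where 7 differential peaks at 286118901 to 286148599 and 7 at 286302401 to 286332899 were 154 kb apart, and on chromosome 3, where 7 at 142569901 to 142592499 and 6 at 142616601 to 142645499 were 24.1 kb apart. The other 3 injury groups held 7 differential peaks each, with no sham peak inside or within 50 kb, on chromosome 7 at 65623801 to 65644499, chromosome 4 at 45370601 to 45399099 and chromosome 16 at 47895701 to 47929399.

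The 10 sham groups with the most peaks held 6 to 23 differential peaks over 6.90 to 78.9 kb. Together they held 132 sham peaks and 2 injury peaks, and 8 of them held no injury peak. Only the groups on chromosomes 2 and 8 also had no injury peak within 50 kb, and the group on chromosome 16 had 9. After the group on chromosome 2, the largest were 12 differential peaks on chromosome 10 at 49186001 to 49233099, where 25 sham peaks faced 1 injury peak, 11 on chromosome 19 at 54367601 to 54393599, where 17 faced none, and 10 on chromosome 10 at 76994501 to 77020899, where each of the 10 sham peaks was differential. The remaining 6 held 6 to 8 differential peaks, on chromosome 14 at 86072101 to 86092599, chromosome 1 at 146786201 to 146801099 and at 85518201 to 85528799, chromosome 16 at 47190801 to 47208999, chromosome 3 at 154887501 to 154900399 and chromosome 8 at 57390801 to 57397699. The sham group on chromosome 16 lay 687 kb from the injury group on that chromosome. None of the 20 groups held a differential peak of the other direction. The groups were chosen for their number of peaks in one list, so their imbalance is not independent evidence of a difference. Their extent depended on the link distance: at 5 kb the largest part of the chromosome 5 group held 7 of its 12 differential peaks and that of the fully differential chromosome 10 group 4 of 10, and at 50 kb both chromosome 3 groups joined into 1 of 13.

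Neighbouring differential peaks had one direction more often than permuted directions gave. Of 1996 pairs of neighbours at most 12500 bp apart, 1888 (94.6%) had one direction and 108 paired an injury with a sham peak. Permuting the directions gave 1016 ± 22.0 such pairs (SD over 10000 permutations), 1097 at the highest, and p = 1e-04 (permutation test, two-sided), the smallest these permutations can give. The share was 98.2% at 5 kb and 87.0% at 50 kb. Only 32.7% of injury and 39.4% of sham differential peaks had any peak of the other list within 12500 bp. That limits the pairs of opposite direction that could arise, and the permutations ignore it, so their p-value says little here. Random draws of peaks outside the differential lists that overlapped no peak of the other list gave a mean share of 68.3% at 12500 bp. Differential peaks were also closer to each other than peaks of their list in general. Injury differential peaks formed 1106 neighbouring pairs, against 681 ± 22.0 in 1000 random draws of as many injury peaks (p = 0.0020), and sham differential peaks formed 783, against 497 ± 19.4 (p = 0.0020, permutation tests, two-sided, and the smallest that 1000 draws can give).

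**Figure D3:**
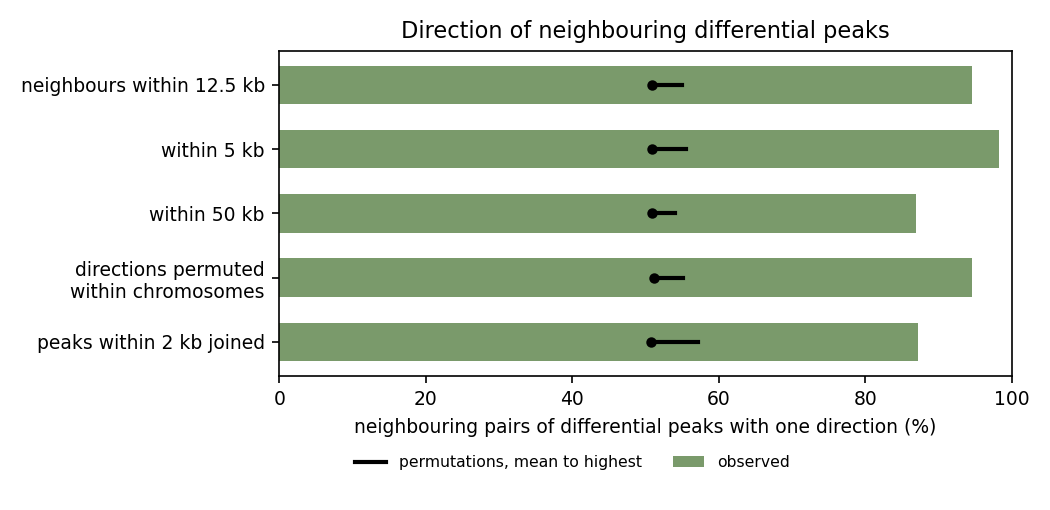
Percent of neighbouring pairs of differential peaks that had one direction (horizontal axis) under 5 settings (rows); bars are the observed values and black lines run from the mean (dot) to the highest of 10000 permutations of the directions. The observed shares were 94.6%, 98.2%, 87.0%, 94.6% and 87.2% from top to bottom, each to the right of its permutations. The permutations ignore how far differential peaks lay from the other list.

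By chromosome, the share of injury differential peaks ranged from 5.61% on chromosome X to 12.6% on chromosome 4. Of the 46044 union peaks, 9.36% were injury differential and 7.15% sham differential. On chromosome 4, 320 of 2541 union peaks (12.6%, 11.4 to 13.9) were injury differential, 1.34 times the number expected (adjusted p = 1.49e-06, Fisher's exact test). On chromosome X the number was 32 of 570 (5.61%, 4.00 to 7.82), 0.599 times the expected one (adjusted p = 0.0146, Fisher's exact test). Of all injury peaks, 32.6% on chromosome 4 and 49.6% on chromosome X overlapped a sham peak, against 39.7% over all chromosomes. Since almost all injury differential peaks overlapped none, these 2 deviations may partly restate how many peaks were called in injury only. The largest deviation over all chromosomes was beyond chance for injury (p = 1e-05, the smallest the permutations can give) and for sham (p = 0.00725, permutation tests). For sham, chromosome 18 (1.37 times, adjusted p = 0.0126), chromosome 5 (1.2 times, adjusted p = 0.0260) and chromosome 2 (1.17 times, adjusted p = 0.0260) lay above the expected number, and chromosome 7 lay below it (0.793 times, adjusted p = 0.0143, Fisher's exact tests). These tests count each peak as independent. With neighbouring union peaks counted once, of the injury results only the low share of chromosome X still passed (0.571 times, adjusted p = 0.0114), chromosome 4 was at 1.18 times (adjusted p = 0.0890), and no chromosome passed for sham (Fisher's exact tests). The largest deviation over all chromosomes then had p = 0.0106 for injury and no longer passed for sham (p = 0.605, permutation tests). When the expected numbers followed covered base pairs, chromosome X no longer passed for injury (0.675 times, adjusted p = 0.0814, exact binomial test), and 1 chromosome lay above and 2 below the expected number for injury, against 4 and 3 for sham.

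**Figure D4:**
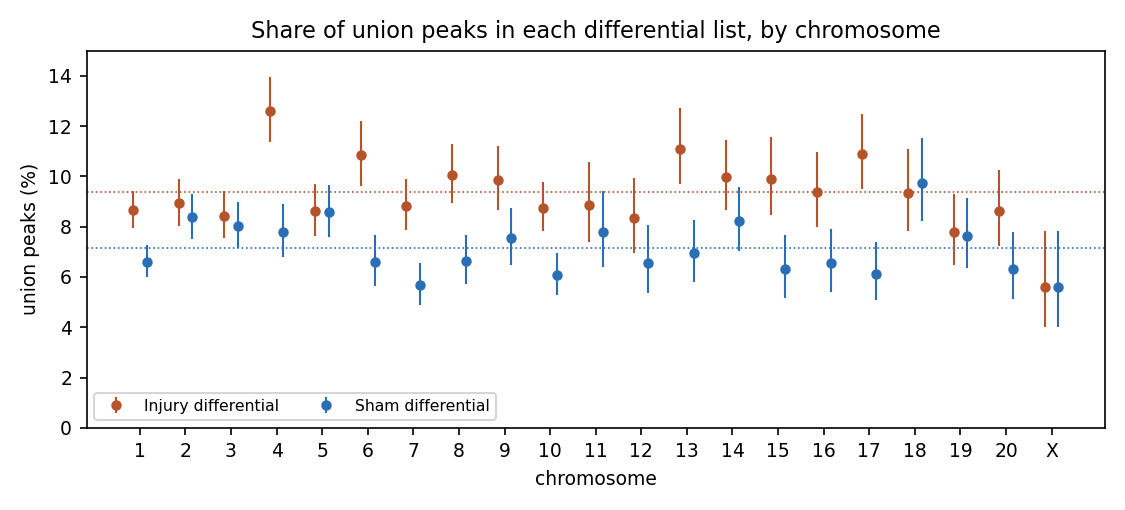
Percent of union peaks (vertical axis) on each chromosome (horizontal axis) that were injury differential or sham differential; points are shares, bars are 95% Wilson intervals and dotted lines mark the shares over all chromosomes, 9.36% and 7.15%. The injury share was 12.6% on chromosome 4 and 5.61% on chromosome X.

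The median width of the differential peaks did not differ between the directions or from the rest of their lists, since all these medians were 299 bp on the 100 bp grid (p = 1, permutation tests). The means did differ. Mean widths were 446 bp for injury differential and 375 bp for sham differential peaks, a difference of 0.22 in mean log2 width (p = 1e-05, permutation test, the smallest these permutations can give). Peaks at the smallest width made up 34.5% of the injury and 48.0% of the sham differential peaks. The full lists differed in the same direction, with 30.2% of the injury and 36.8% of the sham peaks at that width. Injury differential peaks were narrower on average than the other injury peaks, at 446 against 542 bp (−0.19 log2, p = 1e-05), and sham differential peaks narrower than the other sham peaks, at 375 against 483 bp (−0.26 log2, p = 1e-05, permutation tests, two-sided). Of the injury peaks at the smallest width 15.5% were differential, against 8.67% of those over 1 kb, and in the sham list the shares were 15.3% and 6.35%. The comparison of means was added after the tied medians were seen.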

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

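The test of the calling threshold, the comparison of the last lines with whole chromosomes and the leaving out of chromosomes 1 and 14 were chosen after the result was seen. The prediction for the ranking by first and last lines was written beforehand, but its separate blocks were defined from the line order already seen.

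In a column that no comparison uses, the line number of the injury list, 95.4% of the 5320 peaks of chromosomes 1 and 14 stood in the last 20% of the lines, where they made up 79.6% of the peaks against 16.7% of the whole list. In the sham list 19.5% of the peaks of these chromosomes stood in the last 20% of the lines. No biological explanation was tested. A different calling threshold for these chromosomes in injured nerve stays open: the ratio of injury to sham peaks was 1.08 on chromosome 1 and 1.16 on chromosome 14, inside the range of 0.947 to 1.29 over the other chromosomes, but a moderate difference in threshold would also stay inside that range. The order may be a ranking by peak strength made in separate blocks. The share of peaks overlapping sham stands in here for the strength that the lists do not give. From the first to the last 20% of lines this share fell 5.92 percentage points on chromosomes 1 and 14 (Fisher's exact p = 0.00706, two-sided). It fell 11.5 points on the other chromosomes (p = 5.13e-33, Fisher's exact test). Both falls were smaller than that of 27.4 points in the share of sham peaks overlapping injury, along the sham list. Leaving out both chromosomes left the share of neighbouring differential pairs with one direction at 94.6%.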

How the results depend on the processing

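The restrictions of the direction test other than link distance, the counting of neighbours once and the comparison of mean widths were chosen after seeing the data. No paired analysis was possible because the deposited lists hold no value per replicate, although sham and injury samples share the numbers 1 and 2; for the same reason no replicate could be left out. Results for promoters, gene lists and motifs and their other settings were not run, since they need an annotation or sequence of Rnor_5.0. Of the overlap, injury and sham shares were 35.6% and 41.8% with 50% of the shorter peak required and 19.0% and 21.6% with a reciprocal overlap of 50%. They were 52.4% and 60.6% with peaks extended by 500 bp on each side. With both lists cut to peaks wider than their own median, the shares were 38.5% and 52.4%, and the Jaccard index was 0.256 against 0.257 over all peaks. The direction of neighbours stayed past its threshold in all 6 other settings (87.0% to 98.2%), each against permutations that ignore the distance to the other list. Counts of chromosomes past the threshold were 2 for injury and 4 for sham; by base pairs injury had 3 and sham 7, and with neighbouring peaks counted once, injury had 1 and sham 0 (Fisher's exact test; 1 sham chromosome had an unadjusted p under 0.05). Widths differed in mean log2 (0.22, −0.19 and −0.26; p = 1e-05 each, permutation test) where medians tied at a difference of 0; among peaks wider than the median, a choice made on width itself that removes the narrowest peaks and so says little about these differences, medians tied again and mean log2 differed by 0.0049 (p = 0.857), −0.17 (p = 1e-05) and −0.12 (p = 2e-05, permutation tests). Of 40 values for named regions under other link distances, 14 moved by over 1.5 times. Depth is unknown, so no limit from depth could be given.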

Other observations

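Apart from the random draws of unshared peaks, the tests of explanations given here were chosen only after the result or the lists were seen.

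Linking the peaks of both lists at most 12500 bp apart gave 16558 domains. Peaks of both conditions stood in 7465 of them (45.1%), injury peaks alone in 5282 and sham peaks alone in 3811. The domains with both held most peaks, 22882 of the injury and 22450 of the sham list, while 3200 of the injury-only and 2758 of the sham-only domains were a single peak. Differential peaks of both directions met in 148 domains, against 3085 with an injury differential peak and 2416 with a sham differential peak, leaving out the 2 injury differential peaks that are not in the injury list. Of 14 injury-only domains with 10 or more peaks, the largest after the one on chromosome 5 lay on chromosome 20 at 22262301 to 22295799 with 15 peaks, on chromosome 20 at 46189101 to 46225899 with 13, and on chromosome 2 at 217583101 to 217609599 with 13. The largest of 6 such sham-only domains, after the one on chromosome 2, lay on chromosome 1 at 108375601 to 108415099 with 16 peaks, 9 of them differential.

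The injury-only domains on chromosome 20 at 22262301 and on chromosome 2 at 217583101 held 1 differential peak among 15 and none among 13, while the domain on chromosome 5 held 12 among 16. Random placement of the differential calls among the peaks of injury-only domains is argued against: over 171 such domains of 5 or more peaks, the variance of the differential share was 1.64 times the mean of 10000 permutations (p = 1e-04, the smallest they can give, one-sided). The variance does not tell whether domains with few calls were in excess. Of the 171 domains 19 held no differential peak, and the number that random placement gives was not computed. Disagreement between the 2 injury replicates in domains with few calls is a candidate explanation that was not tested, since the lists hold no replicate values.

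Fewer than 50% of the peaks of either list overlapped the other by at least 1 bp, yet 22.0% of the unshared injury and 21.8% of the unshared sham peaks were differential, so called changes do not account for most unshared peaks. Calling of one region as neighbouring pieces at most 1 kb apart does not account for most either. Of the unshared injury peaks outside the differential list 25.4% had a sham peak within 1 kb. Of the sham ones 31.7% had an injury peak within that distance. Pieces with larger gaps, up to the link distance, were not tested and stay open, since domains with both conditions held most peaks of each list. Weak peaks called in one list and missed in the other go with the values, with width standing in for the peak strength that the lists do not give. Midpoints of injury peaks over 1 kb lay inside a sham peak 2.73 times as often as midpoints of the narrowest peaks (47.3% against 17.3%), and the ratio for sham peaks was 2.94. Smaller changes after injury that missed the differential threshold remain open, as does a difference in depth between the libraries, neither of which was tested.

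The shared direction of neighbouring differential peaks was weighed against 4 simpler accounts. One wide peak called in pieces at most 2 kb apart is argued against. After same-direction peaks within 2 kb were joined, 87.2% of pairs still had one direction, above the highest permutation at 57.2%. Pieces with larger gaps, up to the link distance, were not tested. Neither a few large regions nor chromosomes that lean to one direction account for it: the 20 named regions are too small, since 1840 of the 1996 pairs remained without them (94.1% with one direction), and permuting directions within chromosomes gave at most 1099 pairs with one direction, against 1888 observed. Unshared peaks outside the differential lists also lay in such runs, but at 68.3% ± 1.10 (SD over 1000 random draws) and 71.5% at most, so runs are in part a property of unshared peaks in general. The draws were not matched on distance to the other list, so the gap to the 94.6% of differential peaks may partly reflect that distance. A change of whole regions after injury may underlie what remains of the runs. That is an untested hypothesis, since read depth and input signal of these regions were not analysed here. In whole tissue, the lists also cannot tell a change within cells from a change in which cells were present.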
